A study of Mus musculus with 2 samples.

How the data were processed

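Testis RNA of male C57BL/6J mice was sequenced in 2 libraries, with 1 library from testis given a control short hairpin RNA and 1 from testis given a hairpin against Dmrt1, both at 16 weeks of age. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a, featureCounts, Subread 1.5.1, edgeR 3.12.1 and DESeq and the mouse build mm10, with no role or order. Which strand was counted, and which gene annotation was used, are not given in the sources used here.

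The deposited table holds 18722 loci, each with a read count and an FPKM value per library, made by the authors, per the file headers. Of these loci, 17566 carry an Ensembl identifier and 1156 are loci that the table names as new genes. The authors' deposited table also holds a comparison of both libraries by EBSeq, per the file headers, at an FDR of 0.01 and a fold of 2. It gives a value for 15104 loci, which were exactly those with at least 1 CPM (the count relative to the library total) in 1 library. With 1 library per group, the FDRs and calls of that comparison cannot measure a spread between animals. The counts served for every result below. The deposited FPKM values, with a pseudocount of 0.1, served only as an alternative chosen after the data were examined. Every column of values in the table belonged to 1 of the 2 samples or to the authors' comparison and annotation. Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 names, which held 17550 of the 17566 identifiers.

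Counts summed to 17846426 in the control library and 24594371 in the knockdown library. They were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), 1.17 for the control and 0.858 for the knockdown library. A log2 ratio of knockdown over control was computed on the scaled counts with a prior count of 0.5. Its 95% interval is the Clopper-Pearson interval of the knockdown library's share of both counts. Reads carry no molecular identifiers here, so these intervals and all floors cover counting error only. With 1 library per group there was no test between groups, no replicate check and no p-value across genes, and every value compares 2 libraries, not the conditions. The terms higher and lower are therefore used of libraries.

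Before the data were examined, 30 gene lists of textbook markers and pathways were fixed, holding 537 genes, of which 20 stand on more than 1 list and 26 were not analysed here. For each list, the median log2 ratio was taken over members with at least 1 CPM in 1 library, and its percentile was found among 10000 random lists of the same size matched on mean expression in 20 bins. A member counted as higher or lower where its ratio was at least 1.5-fold and its interval excluded 1. Genes across the transcriptome counted as higher or lower where the whole interval lay beyond 2-fold. A gene at 0 counts in 1 library has a bound in place of a ratio, set against 3 counts in that library, which is 0.168 CPM in the control and 0.122 CPM in the knockdown library. List medians with such members are given also with those members at their bound.

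The genes named were chosen by a rule fixed before the data were examined: Dmrt1, Spry1, Nfkb1, Rela and Nfkbia; among genes with an established symbol and at least 100 counts in 1 library, the 12 higher and the 12 lower whose interval bound nearest 0 lay farthest from 0; and up to 4 members of each list by the same measure. Members whose interval spans 0 were to be named only where fewer than 2 others existed. Other genes are said to have been chosen after their values were seen. Some genes that the rule or the lists take are not reported here by name. Alternatives were scaling by library totals, DESeq2 1.42.0 size factors, a prior count of 5, no filter or a filter at 5 CPM, other fold rules, point estimates without an interval, leaving out predicted genes or members of more than 1 list, and means in place of medians.

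The procedure was tested on simulated data. Counts for 15104 genes were drawn at the depths of the control and knockdown libraries, with 200 genes changed in both directions. The draws had Poisson error only, around a profile shared by both libraries. Of 100 genes changed 4-fold, 96% passed the 2-fold rule in the right direction, against 2% of 100 genes changed 2-fold and 0 of 14904 unchanged genes. The intervals held the true ratio for 95.9% of the 15104 genes. A list of 20 genes raised 4-fold lay at percentile 100 and a list of 20 unchanged genes at 88.4. In the real libraries 2685 genes were higher and 3142 lower by the 2-fold rule. The simulation therefore does not test the scaling where so many genes differ, nor any spread between animals. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.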

Results

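The transcriptomes of 2 mouse testis libraries were compared, 1 from testis given a control hairpin RNA and 1 from testis given a hairpin against Dmrt1, a transcription factor of Sertoli cells and spermatogonia. The series title names immune homeostasis of the testis, the gene Spry1 and NF-kB signalling, so these were examined first, followed by the cell types of the testis. The control library held 17846426 counts and the knockdown library 24594371. There were no replicates, and the labels do not say how many testes or animals each library holds.

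Dmrt1 itself (ENSMUSG00000024837, chromosome 19, 25505618 to 25604329 on GRCm38, protein-coding) had 852 counts in the control and 39 in the knockdown library. Its scaled level was 21.9-fold lower in the knockdown library, a log2 ratio of -4.45 (95% counting interval -4.97 to -4.01). Spry1 (ENSMUSG00000037211, chromosome 3, 37639947 to 37644598, protein-coding), an inhibitor of receptor tyrosine kinase signalling, had 389 and 209 counts and was 1.89-fold lower, with a log2 ratio of -0.91 (-1.17 to -0.67). The authors' deposited table gives Dmrt1 a log2 fold change of -4.41 and calls it down, and gives Spry1 -0.92 and the call normal. Those calls compare 1 library per group and hold no spread between animals. The list of Sprouty, Spred and MAPK feedback genes that holds Spry1 went both ways. Of its 15 measured members, 5 were at least 1.5-fold lower, 3 were higher and 7 were neither, with a median log2 ratio of -0.16 at percentile 34.7 of random lists. Scaled by library totals, 7 were lower and 1 higher. Among the lower ones were Spry4 at -2.43, Etv5 at -2.11 and Etv1 at -1.14, the last 2 being transcription factors. Egr1, an immediate early gene, was higher at 1.61.

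Genes of the NF-kB pathway were mostly higher in the knockdown library, in which immune cell markers were higher too. The list medians were 2.79 for macrophages and monocytes and 3.16 for T and NK cells. For neutrophils the median was 8.36, or 6.63 with members at 0 counts at their bound. The inhibitor gene Nfkbia, itself a target of the pathway, was 3.84-fold higher (log2 1.94, interval 1.87 to 2.02). Nfkb1 was 2.93-fold higher (1.46 to 1.64 on the log2 scale) and Rela 1.62-fold higher (0.62 to 0.78). The authors' deposited table calls all 3 normal, again from 1 library per group. Its log2 fold changes were 1.93 for Nfkbia, 1.54 for Nfkb1 and 0.68 for Rela. Of 34 measured signalling components, 25 were higher, 2 lower and 7 neither, and their median of 1.01 lay above all 10000 random lists. Scaled by library totals, 16 were higher, 3 lower and 15 neither, with a median of 0.57. The tumour necrosis factor receptor gene Tnfrsf1b had a log2 ratio of 4.68, the Toll-like receptor gene Tlr2 4.56, the feedback inhibitor Tnfaip3 3.80 and Traf1 3.08. The 2 lower components, chosen after their values were seen, were the interleukin receptor gene Il1r1 at -2.92 and the kinase gene Chuk at -0.76. Of 25 measured target genes, 23 were higher and 2 lower, with a median of 3.33, which was the same with the member at 0 counts at its bound, and above all 10000 random lists. Nos2, which makes nitric oxide, was 416-fold higher, from 50 to 21313 counts. The chemokine gene Ccl5 was 67.6-fold higher and Il1b 62.4-fold higher. Both lower targets, again chosen after their values were seen, were Lcn2, 37.1-fold lower from 90859 to 2480 counts, and Vcam1, 6.67-fold lower from 20766 to 3159 counts.

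Transcripts of immune cells were higher in the knockdown library for every immune cell list, though not for every macrophage marker. All 13 neutrophil markers were higher. Their median was 8.36, or 6.63 with the 5 members at 0 control counts at their bound, above all 10000 random lists. S100a8, a subunit of calprotectin, had 0 and 4771 counts and was at least 1568-fold higher. S100a9 had 1 and 7560 counts, a log2 ratio of 12.28 (10.39 to 18.17), and Ngp 1 and 2644 counts, a log2 ratio of 10.77 (8.87 to 16.65). Retnlg was at least 188-fold higher. All 19 measured T and NK cell markers were higher, with a median of 3.16 above all random lists. The granule protease gene Gzmb was 45.5-fold higher, Cd8a 13.9-fold, Cd3d 13.5-fold and Nkg7 12.8-fold. Of 20 measured macrophage and monocyte markers, 17 were higher, 2 lower and 1 neither, with a median of 2.79 above all random lists. The Fc receptor chain gene Fcer1g was 34.0-fold higher, the lysosomal marker Cd68 32.4-fold, Itgam 22.8-fold and Tyrobp 16.3-fold. The lower pair, chosen after their values were seen, were Cd163 at -4.43 and the mannose receptor gene Mrc1 at -1.61. All 9 measured B and plasma cell markers were higher, with a median of 1.06 at percentile 97.6, and 5 of the 9 were higher when scaled by library totals. Cd22 had a log2 ratio of 2.57, Cd79b 1.62, Ms4a1 1.20 and Mzb1 1.06.

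Inflammatory mediators and antigen presentation genes were higher as well. Of 31 measured cytokine and chemokine genes, 28 were higher, 1 lower and 2 neither. Their median of 2.89, unchanged with 2 members at their bound, lay above all 10000 random lists. Tnf was 46.3-fold higher, from 53 to 2511 counts, and the neutrophil attractant gene Cxcl2 had 0 and 335 counts, at least 110-fold higher. Of 26 measured interferon response genes, 25 were higher and 1 neither, with a median of 2.91 above all random lists. The antiviral gene Rsad2 was 136-fold higher, Oasl1 24.9-fold, Gbp2 16.5-fold and Ifit2 15.5-fold. All 16 antigen presentation genes were higher, with a median of 2.98 above all random lists. The class II genes H2-Aa and H2-Eb1 were 310-fold and 213-fold higher, against 16.3-fold for H2-Ab1 and 10.9-fold for the invariant chain gene Cd74. Class II genes belong to a family of similar sequences, so reads of one can be counted for another. Of 12 measured complement genes, 9 were higher, 2 lower and 1 neither, with a median of 1.21 at percentile 98.3. C2 was 20.8-fold higher, the receptor gene C5ar1 11.3-fold and C3 3.92-fold by counts but 7.53-fold by FPKM, whereas Cd59a, which protects cells from complement, was 5.39-fold lower.

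**Figure D1:**
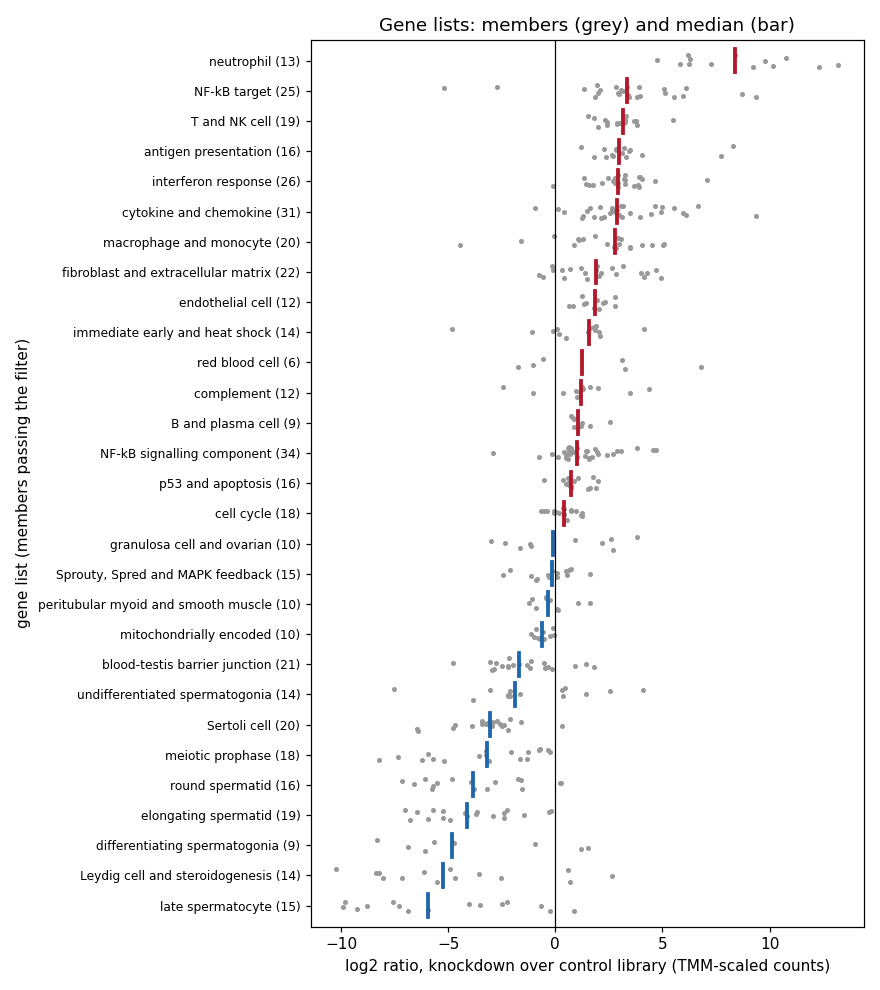
Log2 ratio of the knockdown over the control library for the members of 29 gene lists (grey points, TMM-scaled counts, members with at least 1 CPM in 1 library, vertical scatter for legibility only) with the median of each list (bars, red above 0 and blue below 0); members at 0 counts in 1 library are drawn at the ratio set by the prior count. The neutrophil median of 8.36 is the highest and the late spermatocyte median of -5.95 the lowest as drawn. With members at their bound the late spermatocyte median is -4.29, and the Leydig median of -5.23 is then the lowest. The epididymis list, with 1 measured member, is not drawn.

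Leydig cell transcripts were far lower in the knockdown library. Of 14 measured genes of Leydig cells and steroidogenesis, 11 were lower and 3 higher, with a median of -5.23 below all 10000 random lists. The 15 list genes found in the deposited table, with or without passing the filter, made up 25425 CPM of the control and 545 CPM of the knockdown library. Of these, Insl3, named after its values were seen, held 11327 and 180 CPM. Cyp17a1, which makes androgen precursors, had 83928 and 280 counts and was 303-fold lower on the scaled counts. Hsd3b1 was 332-fold lower and Hsd17b3 267-fold lower. The luteinising hormone receptor gene Lhcgr had 4128 and 3 counts, a log2 ratio of -10.22 (-12.72 to -8.90). Among the higher members, Hsd11b1 at 2.64 and Stard4 at 0.70 were chosen after their values were seen, and 1 of the 3 stayed at least 1.5-fold higher with library totals.

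Sertoli cell transcripts were lower too. Of 20 measured markers, 19 were lower and 1 was neither, the protease gene Ctsl, named after its value was seen, and the median of -3.05 lay below all random lists. Rhox5 was 87.7-fold lower, Cst9 84.3-fold, the gap junction gene Gja1 27.6-fold and the follicle-stimulating hormone receptor gene Fshr 25.9-fold. Of 21 junction genes of the blood-testis barrier, 14 were lower, 3 higher and 4 neither, with a median of -1.70 below all random lists. Espn was 8.19-fold lower, Cgn 7.68-fold and the cadherin gene Cdh2 7.25-fold. Genes of granulosa cells and ovary, the female counterpart of Sertoli cells, went both ways, with 5 of 10 measured members higher and 5 lower. Their median of -0.11 (percentile 36.6) and mean of 0.29 had opposite signs. The list held 16 genes. Those not measured, named after their values were seen, were Foxl2, Esr2, Cyp19a1, Irx3, Irx5 and Lgr5, with less than 1 CPM in both libraries. Bmp2 had a log2 ratio of 3.79 and Runx1 2.69, against -2.99 for Nr0b1 and -2.33 for the oestrogen receptor gene Esr1.

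Most fibroblast and all endothelial list members, by contrast, were higher in the knockdown library. Of 22 fibroblast and extracellular matrix genes, 16 were higher, 2 lower and 4 neither, with a median of 1.92 above all random lists. Lum was 30.6-fold higher, the collagen cross-linking enzyme gene Lox 26.3-fold, Col1a1 19.7-fold and Col3a1 17.9-fold. The 2 lower members, chosen after their values were seen, were Pdgfra and Timp1. All 12 endothelial markers were higher, with a median of 1.87 at percentile 99.98, and with library totals 10 were higher and 2 neither. Eng was 6.86-fold higher, Vwf 6.83-fold, Pecam1 5.04-fold and Egfl7 4.66-fold. Cdh5 and Kdr, chosen after their values were seen, had the smallest ratios of the 12. Among 10 peritubular myoid and smooth muscle genes, 2 were higher, 3 lower and 5 neither, with a median of -0.34 at percentile 18.7, and with library totals 6 were lower. Tagln had a log2 ratio of 1.62 and Synpo2 1.08, against -1.23 for Mylk and -1.09 for Cnn1, which was -0.15 by the deposited FPKM values.

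**Figure D2:**
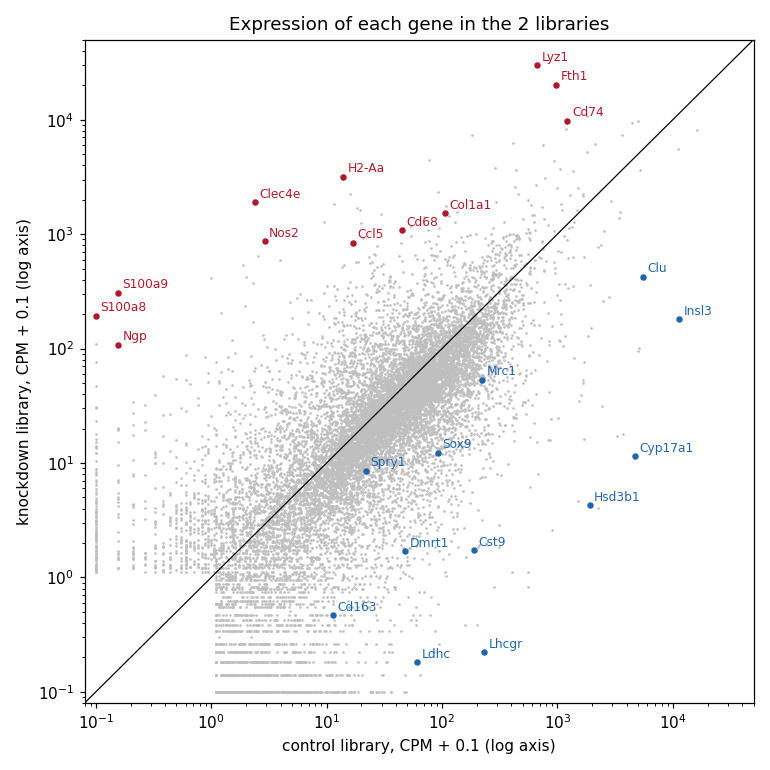
Level of each gene with at least 1 CPM in 1 library, in CPM of the library total plus 0.1, in the control (x axis, log) and knockdown library (y axis, log), with the line of equal CPM; grey points are genes and coloured points are examples, red for higher and blue for lower in the knockdown library. Insl3, Clu, Sox9, Mrc1, Cd163, Lyz1 and Fth1 were chosen after their values were seen.

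Germ cell transcripts were scarce in both libraries, the control included, and scarcer in the knockdown library. The 121 germ cell genes analysed made up 0.166% of the control and 0.0475% of the knockdown counts, or 1661 and 475 CPM. Part of that difference lay in genes that other testis cells also express. Kit held 374 CPM of the control and 9.72 of the knockdown library, and Etv5, also on the Sertoli list, 75.7 and 12.9. Of 14 measured genes of undifferentiated spermatogonia, 8 were lower, 3 higher and 3 neither, with a median of -1.88 (percentile 0.18), the same with 1 member at its bound. Zbtb16 was 14.3-fold lower and Uchl1 8.37-fold lower, and Sall4 had 90 and 0 counts, at least 30.4-fold lower, while Upp1 was 17.2-fold higher. Of 9 genes of differentiating spermatogonia, 7 were lower and 2 higher, with a median of -4.82 (percentile 0.37), or -4.27 with 3 members at their bound. The receptor kinase gene Kit, which Leydig cells also express, was 28.3-fold lower, and Dmrtb1 at least 54.1-fold lower. Of 18 genes of meiotic prophase, 16 were lower and 2 neither, with a median of -3.17 (percentile 0.09), the same with 3 members at their bound. Syce1, of the synaptonemal complex, was at least 50-fold lower, and Sycp2 was 36.6-fold lower.

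Late spermatocyte genes had a median of -5.95, below all random lists, or -4.29 with 4 members at their bound. Of 15 measured, 13 were lower, 1 higher and 1 neither. Ldhc, a lactate dehydrogenase of sperm, had 1085 and 2 counts, a log2 ratio of -8.78 (-12.15 to -7.25), and Tdrd1 was at least 164-fold lower. Of 16 round spermatid genes, 14 were lower and 2 neither, with a median of -3.86 (percentile 1.11), or -3.15 with 4 members at their bound. Adam2 had 212 and 1 counts, a log2 ratio of -7.16 (-13.06 to -5.25). Of 19 elongating spermatid genes, 17 were lower and 2 neither, with a median of -4.13 (percentile 0.28), the same with 2 members at their bound. The protamine gene Prm2 had 91 and 1 counts, a log2 ratio of -5.95 (-11.85 to -4.01). Meig1 was 38.1-fold lower. The matched random lists were themselves lower, with medians of -1.35 for round spermatids and -1.01 for elongating spermatids. Those for differentiating spermatogonia and meiotic prophase were -0.66 and -0.62. For late spermatocytes and undifferentiated spermatogonia they were -0.32 and -0.12. Scarce genes can pass the filter through the control library alone, so part of the lower germ cell ratios can come from the filter.

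Stress, cell cycle, red blood cell and organelle lists were compared last. Of 16 p53 and apoptosis genes, 13 were higher and 3 neither, with a median of 0.73 at percentile 98.5, against 6 higher and 1 lower with library totals. The cell death genes Apaf1 and Fas had log2 ratios of 2.01 and 1.92. Of 18 cell cycle genes, 6 were higher, 1 lower and 11 neither, with a median of 0.39 at percentile 90.1 that was -0.049 when scaled by library totals, with 3 higher and 3 lower. Pcna had a log2 ratio of 1.27 and Mki67 0.97. Of 14 immediate early and heat shock genes, 8 were higher, 2 lower and 4 neither, with a median of 1.57 above all random lists. Atf3 was 17.5-fold higher, whereas the chaperone gene Hspa1a was 28.1-fold lower. Of 6 red blood cell genes, 3 were higher, 2 lower and 1 neither, with a median of 1.25 at percentile 97.6, the same with 1 member at its bound. The globin genes Hba-a1 and Hbb-bs were 9.49-fold and 8.52-fold higher, and Alas2, which starts haem synthesis in red cell precursors, was 3.30-fold lower. Of 10 mitochondrially encoded genes, 5 were lower and 5 neither, with a median of -0.64 at percentile 0.36, and 8 were lower with library totals. The subunit gene mt-Nd5 had a log2 ratio of -1.12. The epididymis list had 1 measured member, Cuzd1, 5.68-fold lower at percentile 17.7.

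Across the transcriptome, 2685 of 15104 genes were more than 2-fold higher in the knockdown library and 3142 more than 2-fold lower, over their whole counting interval. Library totals in place of TMM lowered the log2 ratios by a median of 0.44, and then 1922 were higher and 4202 lower. Higher genes were 46.1% of those past the rule with TMM and 31.4% with library totals. The authors' deposited table calls 1589 loci up, 2140 down and 11375 normal. All 1589 and 2140 lay past the 2-fold rule in the same direction. Besides the genes above, the 12 with the highest conservative ratios included the C-type lectin receptor genes Clec4e, 1108-fold higher, and Clec4d, 605-fold higher, the formyl peptide receptor gene Fpr2, 402-fold higher, Ly6i, 353-fold higher, and the coagulation factor gene F10, 298-fold higher. Slc6a12 had 0 control counts and was at least 377-fold higher. The 12 lowest included, besides the Leydig genes above, the steroid hydroxylase gene Cyp21a1, 542-fold lower, the prostaglandin synthase gene Ptgds, 410-fold lower, the oestrogen sulphotransferase gene Sult1e1, 394-fold lower, Snhg11, 482-fold lower, Pgbd5, 290-fold lower, and Bhmt, 242-fold lower. Tuba3b had 870 and 0 counts, at least 294-fold lower, and Trpc5os 1160 and 1 counts, a log2 ratio of -9.61 (-15.51 to -7.72).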

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

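The authors' FPKM values in place of counts, and members at 0 counts set at their bound, were tried only after the data were examined. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. None of the 131 other named genes, and neither Dmrt1 nor Spry1, changed sign under any alternative run for them. DESeq2 size factors left all 131 named genes inside their counting intervals, library totals moved 80 beyond them, a prior count of 5 moved 24 and FPKM moved 39. FPKM moved the ratio by over 1.5 times for C3, Cnn1, Insl3 and Fam107b. Among the other genes with a ratio in the text, it did so only for some with at most 9 counts in 1 library. Under the 4-fold rule, 1266 genes were higher and 1785 lower, a stricter rule by construction; the counts stayed within 1.5 times the main ones under the other alternatives, from 1922 to 3736 for higher genes and from 2241 to 4202 for lower genes. Library totals, which lower all ratios alike, put Spry1 at -1.36 and moved the medians to -3.49 for Sertoli cells, 0.62 for B and plasma cells, 0.57 for NF-kB signalling components, 2.47 for the interferon response, 0.28 for p53 and apoptosis, -0.049 for the cell cycle and -1.08 for mitochondrially encoded genes. A prior count of 5 moved the neutrophil median to 5.95. Of its 13 members, 5 had 0 control counts and others 1 or 2, where a larger prior count draws ratios towards 0 by construction. The epididymis list rests on 1 gene and its median of -2.51 moved to -2.94 with library totals, -2.50 with DESeq2 size factors, -1.59 without a filter, -2.28 with a prior count of 5 and -2.32 with FPKM. The medians of the other 29 lists stayed within a 95% interval under DESeq2 size factors, both filters, FPKM, means, and leaving out members of more than 1 list. That interval of the median came from the ranked ratios of a list's members. It was wide for some lists, -8.25 to 0.59 for Leydig genes and -1.72 to 6.81 for red blood cell genes. Staying inside it says little there. For the granulosa list, whose members go both ways, it was wide too, -2.33 to 2.69. The granulosa median of -0.11 was 0.94 with the filter at 5 CPM, -1.16 without members of other lists and 0.0049 with a prior count of 5. Its direction is therefore not settled. Depth limits lists with members at 0 counts. In the control library these were 5 of 13 for neutrophils, 2 for cytokines and chemokines, 1 for NF-kB targets and 1 for red blood cells, and in the knockdown library 1 to 4 members of each germ cell list.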

Other observations

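The lists, the tests and the genes outside the naming rule below were chosen after the data were examined, except the test of overlapping exons, which was written before its result was seen. Macrophage genes beyond the fixed list are given as values, since both lists were picked in part on these libraries and test no split between kinds of macrophage. Of 19 genes typical of resident or alternatively activated macrophages, a list written after Mrc1 and Cd163 were seen to be lower, 10 were at least 1.5-fold lower in the knockdown library, 4 higher and 5 neither, with a median log2 ratio of -1.61. Retnla had 167 and 3 counts, a log2 ratio of -5.60 (-8.11 to -4.25), and Mrc1 was 3.05-fold lower, whereas Lyve1 was 18.3-fold higher and F13a1 4.07-fold higher. All 19 genes of a list of activated macrophages, several of them picked because they were high, were higher, with a median of 5.11. Marco, a scavenger receptor gene, was 229-fold higher and Acod1, which makes itaconate, 207-fold higher. Lysosome and iron storage genes took up much of the knockdown library. Of 21 such genes, 20 were higher, and together they made up 0.895% of the control and 9.62% of the knockdown counts. The ferritin gene Fth1 was 28.3-fold higher and the cathepsin gene Ctss 55.4-fold higher. Lyz1, with 2.99% of the knockdown counts, had more counts than any other gene of that library and was 60.8-fold higher, although reads of its near copy can be counted for it. Of 8 genes of mast cells and eosinophils, 7 had 0 control counts and few counts in the knockdown library, where Prg2 had 217 counts and Cpa3 69, at least 71.3-fold and at least 22.7-fold higher. Siglecf had 9 and 13 counts. The 6 that passed the filter, all through the knockdown library, had a median of 4.06 at their bounds.

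Pathways in the authors' annotation went both ways. Of 255 KEGG pathways with at least 15 measured genes, which share many genes, 89 had a median above percentile 99 of random matched lists and 31 below percentile 1. Steroid hormone biosynthesis had the lowest median, -2.37 over 23 genes, followed by cytochrome pathways of drug metabolism at -1.96. In fatty acid degradation 29 of 40 genes were more than 2-fold lower and in valine, leucine and isoleucine degradation 31 of 46. Of 16 measured cholesterol synthesis genes 11 were lower, with a median of -0.87, and Sqle was 2.51-fold lower. Other metabolic pathways were higher, such as glycosaminoglycan degradation with a median of 1.22 and starch and sucrose metabolism with 1.01. Ribosome genes were higher, with 82 of 132 more than 2-fold higher and a median of 1.36, while ribosome biogenesis had a median of -0.03. The NF-kappa B pathway of that annotation had 54 of 93 genes more than 2-fold higher and 5 lower, with a median of 1.53. In the same library Leydig and Sertoli markers were lower, with medians of -5.23 and -3.05, and immune cell markers were higher. Pathway ratios were not separated from the cell make-up of the libraries.

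Protamine and transition protein genes, which spermatids express at high levels, had few counts in the control library itself. Prm1 had 43 counts, Prm2 91 and Tnp1 55 of 17846426, so the ratios of germ cell genes compare 2 libraries with few spermatid transcripts. The labels do not say whether germ cells had been depleted. Insl3 of Leydig cells took 1.13% of the control counts and Clu of Sertoli cells 0.546%. H2-Aa had 1.13 counts per 100 counts of Cd74 in the control and 32.3 in the knockdown library.

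Immune transcripts were higher and Leydig and Sertoli transcripts lower in the knockdown library. Dilution of all testis cells alike by added immune RNA would lower their list medians together. The Leydig, Sertoli, myoid, fibroblast and endothelial medians, known when this comparison was chosen, spanned 7.15 log2 units, which argues against it. Fibroblast and endothelial list genes that immune cells also express could widen that span. The Leydig, Sertoli and myoid medians alone were -5.23, -3.05 and -0.34. Residual blood as the main source of the immune transcripts as a whole was examined through the globin transcripts. These gained 195 CPM against 10334 CPM for 61 immune cell genes, a ratio of 0.0189. The globin sum of the knockdown library rests on Hba-a1 (98.8 CPM) and Hbb-bs (132 CPM). Both have near copies, and how reads matching 2 genes were counted is not given in the sources used here. The ratio therefore argues against blood as the main source only if globin reads were counted in full. A small share of blood is not excluded by it in any case. Most of the immune gain lay in macrophage and monocyte genes (1934 CPM in the control, 9895 in the knockdown library). The neutrophil list rose from 11.7 to 1005 CPM. In the knockdown library S100a8 and S100a9 held 501 CPM and the globins 231 CPM, so blood as a source of neutrophil transcripts was not decided. Exchanged labels cannot be told apart from the labels as given by Dmrt1 alone, at -4.45 in the library labelled as its knockdown, since 4 of 20 Sertoli markers were as low or lower there. The effect of the knockdown, a difference between the tissue of the 2 libraries unrelated to it, and a reaction to the procedure were not tested against each other, since each group has 1 library and the labels do not say how many testes or animals it holds.

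Dmrt1 was lower together with the markers of the cells that carry it. Fewer such cells, without any loss per cell, predict a Dmrt1 ratio inside the range of Sertoli markers. Of 20 Sertoli markers, 4 were at or below Dmrt1. That range, from -6.45 for Rhox5 to 0.31 for Ctsl, was wide, so the prediction could hardly fail. Marker levels also do not separate fewer cells from lower expression per cell. A lower number of Dmrt1-carrying cells was therefore neither shown nor excluded. Dmrt1 lay 1.40 log2 units below the Sertoli median, which leaves room for a loss within cells, and spermatogonia, which also carry Dmrt1, were not separated from Sertoli cells. Spry1 lay 2.13 above the Sertoli median, and 19 of 20 Sertoli markers were lower than it.

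The deposited counts and FPKM values gave ratios more than 2-fold apart for 39 of 10298 genes with at least 100 counts in both libraries. Insl3 was 46.3-fold lower by counts and 264-fold lower by FPKM, and Fam107b had a log2 ratio of 2.52 by counts and -0.66 by FPKM. Reads shared with genes whose exons overlap are argued against as the general source, since 3 of the 39 (7.69%, Clopper-Pearson 95% interval 1.62% to 20.9%) overlapped another gene of the table against 18.2% of the others, a ratio of 0.424. That share does not decide the source for any single gene, Insl3 included. How FPKM was computed is not given in the sources used here, and no biological explanation was tested.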
